A study of Mus musculus with 2 samples.

How the data were processed

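Gene expression was measured on 2 microarrays, 1 for each of 2 genotypes of mice. Per the labels' protocols, mice aged 8 to 12 weeks were exposed to ultraviolet light for 30 min, and 21 days later cells carrying both Langerin and Epcam were sorted as Langerhans cells. The labels' protocols also state that cells were sorted straight into lysis buffer, that RNA was isolated with a column kit for small samples, and that biotinylated cRNA was made from 2 ng of total RNA. The platform named with the probe annotation is an Affymetrix mouse whole-transcript gene array, which reads probes along a gene and has 1 colour. The labels do not say whether RNA of 1 animal or of several was used for each array.

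The authors deposited 1 processed intensity per probe set and array, on a linear scale. How probes were combined into probe sets, how background was removed and how the 2 arrays were scaled are not given in the sources used here. The scale was read from the values, which are all above 0, strongly skewed and reach 13748.0 in Il34+/LacZ and 13767.9 in Il34LacZ/LacZ. The 2 columns do not share their quantiles, so no quantile normalization is present in this form. Scanner files and detection calls were not analysed here, so no probe set could be called present or absent.

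The table held 34760 probe sets. The platform annotation gave 21640 of them 1 gene symbol, 1321 several symbols and 11799 none. Only probe sets with 1 symbol were named. The RefSeq gene table of assembly GRCm38.p6 listed the gene number of 21553 of them, with the same symbol in 21553 cases. They covered 19937 genes, of which 954 had more than 1 probe set. A gene was represented by the probe set with the highest mean of the 2 arrays.

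Values were transformed as log2(intensity + 16), and differences are Il34LacZ/LacZ minus Il34+/LacZ. Folds are on this scale, so they understate the change of dim genes. A gene was used if the higher of its 2 levels was at or above the median of all probe sets over both arrays, an intensity of 48.7, called the floor below. 12843 genes passed. Where the dimmer array was below the floor, the fold was computed against the floor and is given as a lower bound. Because the difference depended on the level of a gene, each result was also computed after a loess trend of the difference on the mean level was removed. That trend was fitted to probe sets with 1 symbol, with a smoothing fraction of 0.3. Its removal sets the typical gene of each level to no difference.

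With 1 array per genotype there is no test between genotypes, and no p-value is given. The files hold a single measure of error, the disagreement between different probe sets of one gene. It was 0.61 on the log2 scale (SD of a gene's difference, from 610 genes with 2 or more probe sets at or above the floor), or 1.53-fold. It covers probe noise and isoform differences, not animals, sorts or amplifications. Gene lists were described by their median, by the number of members at least 1.5-fold apart, and by the percentile of the median among 10000 random lists of the same size, drawn from genes of the same level in 20 bins. These percentiles describe these 2 arrays only.

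The lists, the floor, the 2-fold threshold, the rule for named genes and all alternatives except 2, named with the effect of the processing, were fixed before the data were examined. Named genes were the 12 with the largest difference in each direction, leaving out predicted and clone names and genes whose other probe sets disagreed in direction. Il34, Csf1r, Csf1, Cd207, Epcam, Cd74, Ptprc and Xist were named whatever their values, as were up to 4 members of each list with the largest difference. The lists covered Langerhans cell identity, monocytes, macrophages, the CSF1 receptor pathway, antigen presentation by MHC class I and II, dendritic cell maturation, interferon responses, inflammatory cytokines, immediate early genes, cell cycle, survival, p53 targets, the TGF-beta pathway, cholesterol, energy metabolism, ribosomal proteins, the unfolded protein response, lysosomes, sex-linked genes, chromosomal neighbours of Il34, control genes and the other cell types a skin sort could hold. A platelet list was added after the first values were seen.

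The scripts were tested on simulated data for this comparison, with the 12843 real levels, the probe set noise above and the real trend with level. The noise was drawn separately for each gene, with the same SD at every level. Of 50 genes changed 2-fold, 38.0% passed the 2-fold threshold as deposited, against 94.0% of those changed 4-fold. Among the unchanged genes of the simulation, 665 appeared at least 2-fold higher and 1402 at least 2-fold lower, and 5 and 49 at least 4-fold. Of 40 simulated lists of 20 unchanged genes, 2 lay outside the central 95% of random lists, and 38 of 40 lists lowered 1.5-fold lay below it. Alternatives changed the floor, the probe set rule, the scaling and the pseudocount. Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1, statsmodels 0.14.6 and matplotlib 3.10.9 were used.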

Results

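Langerhans cells, the Langerin-positive antigen-presenting cells of the epidermis, were compared between mice with 1 working copy of Il34 (Il34+/LacZ) and mice with a LacZ cassette in both copies (Il34LacZ/LacZ). IL-34 is a ligand of the CSF1 receptor and is made in skin mainly by keratinocytes. The comparison asks how Langerhans cells present 21 days after ultraviolet exposure differ when the animal lacks IL-34. Each genotype was measured on 1 array (n = 1), so each value below is a single measurement with no replicate error. Probe sets of one gene disagreed by an SD of 0.61 on the log2 scale, and differences under about 1.53-fold lie within 1 such SD. Median intensity was 45.2 on the Il34+/LacZ array and 51.9 on the Il34LacZ/LacZ array. The upper quartile was 142.7 and 116.4, and the 95th percentile 736.4 and 513.2, respectively.

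The targeted gene was near the floor in both samples. Il34 read 39.4 in Il34+/LacZ and 64.4 in Il34LacZ/LacZ, a difference of 0.54 that is within the probe set SD. The position of its probes relative to the cassette is not known here, and Langerhans cells are not its main source, so the reading does not check the labels. Among the genes furthest apart were the keratin gene Krt14, 10.8-fold lower in Il34LacZ/LacZ, and S100a8 and Pf4, 6.46-fold and 6.04-fold higher there. Cell cycle genes were lower, with a median of -0.91 over 28 genes and -0.56 with the trend with level removed, and inflammatory genes lay above others of their level. Langerhans cell identity genes, with a median of -0.67 over 21 genes and -0.06 with the trend removed, differed about as much as other genes of their level.

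Most well-expressed genes read lower in Il34LacZ/LacZ. Of 12843 genes at or above the floor, 327 were at least 2-fold higher and 1685 at least 2-fold lower, and 17 were at least 4-fold higher and 85 at least 4-fold lower. The median difference was 0.30 for probe sets between 16 and 48 intensity units, -0.65 between 240 and 496, and -0.25 above 4080. With this trend removed, 530 genes were at least 2-fold higher and 892 lower, so higher genes made up 37.3% of those apart in place of 16.3%. 216 genes were at least 2-fold higher and 706 lower by both measures. Levels of the 2 arrays correlated across genes with Pearson r = 0.848 and Spearman rho = 0.767; genes are not independent replicates. Simulated unchanged genes, with the real trend and a noise SD of 0.61 at every level, gave 665 higher and 1402 lower at 2-fold. They gave 616 and 649 with the trend removed, and 5 higher and 49 lower at 4-fold as deposited. The 2-fold higher counts were thus below the simulated ones and the lower counts above them. At 4-fold the counts were above the simulated ones in both directions, also with the trend removed. The SD of the real differences was 0.393 between 16 and 48 intensity units, 0.695 between 112 and 240, and 0.224 above 4080. With 1 SD for all levels, the simulation does not set the number of false calls. Folds below are as deposited, so for genes of middle and high level they include the trend.

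**Figure D1:**
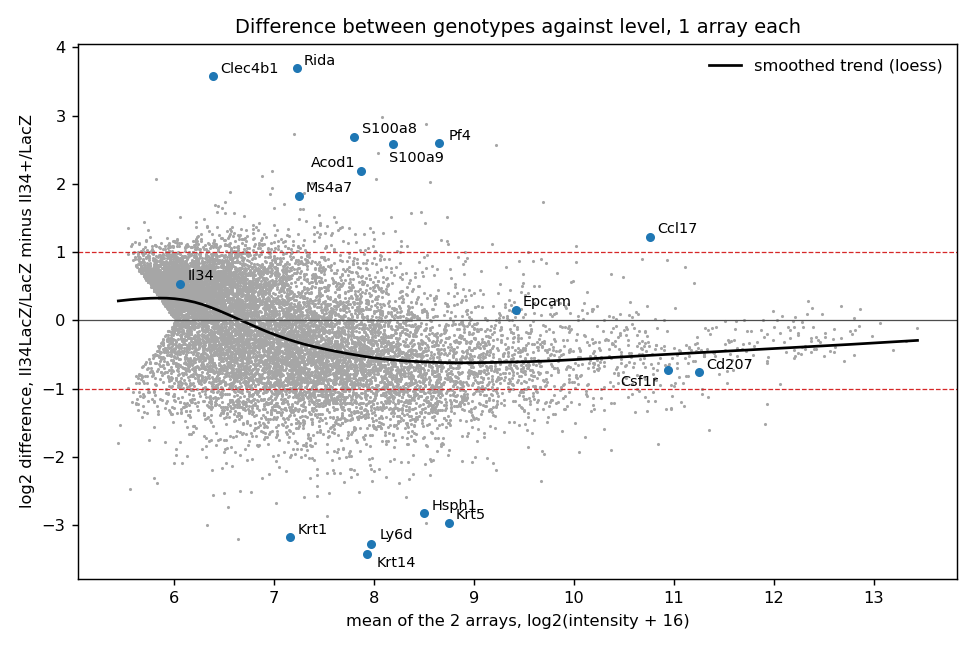
Log2 difference between Il34LacZ/LacZ and Il34+/LacZ (y) against the mean log2(intensity + 16) of the 2 arrays (x); each grey point is 1 of 12843 genes, dashed lines mark 2-fold, and blue points are labelled genes. The black loess trend lies above 0 for dim genes and below 0 for genes of middle and high level, while Krt14 at -3.43 and Pf4 at 2.60 lie far from it.

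Cd207, which encodes Langerin, read 3153.0 and 1852.0 (difference -0.76, -0.29 with the trend removed), Epcam, the sorting marker, 632.9 and 707.7 (difference 0.16, 0.77 with the trend removed), and Cd74, the MHC class II invariant chain, 7514.1 and 6837.0 (difference -0.14, but 0.21 with the trend removed). Ptprc, the pan-leukocyte CD45, read 1345.6 and 1078.2 (difference -0.32, but 0.24 with the trend removed). Of 21 measured Langerhans cell identity genes, 12 were at least 1.5-fold lower in Il34LacZ/LacZ and none was higher, but 2 were lower and 1 higher with the trend removed. Their median of -0.67 lay at the 8.91 percentile of random lists of the same level and was -0.06 with the trend removed, so the list lay within the central 95% of random lists either way. Sirpa, an inhibitory receptor of myeloid cells, was 2.32-fold lower and Tgfbr1, a TGF-beta receptor that Langerhans cells need, 2.19-fold lower. Plek2 was 2.14-fold lower and Gpr55, near the floor, at least 2.00-fold lower. Tgfbr1 and Plek2 differed by -0.53 and -0.48 with the trend removed, within the probe set SD, and Sirpa by -0.67. Gpr55, below the floor in Il34LacZ/LacZ, differed by -1.20 with the trend removed.

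The receptor for IL-34 was read far above the floor in both samples. Csf1r read 2507.3 in Il34+/LacZ and 1510.7 in Il34LacZ/LacZ, a difference of -0.73 that was -0.23 with the trend removed. Csf1, the other ligand of the receptor, read 66.3 and 123.8 (difference 0.76, 0.81 with the trend removed), near the floor. Of 18 measured genes of the CSF1 receptor list, 9 were at least 1.5-fold lower and 2 higher, with a median of -0.61 at the 24.76 percentile. Once the trend was removed, 4 were lower and 3 higher, with a median of -0.05. As deposited, the members furthest apart were other cytokine receptors and an adaptor. Csf2rb2, a beta chain of the interleukin-3 receptor, was 3.04-fold lower, the stem cell factor receptor Kit 2.66-fold lower, Flt3, the receptor of the dendritic cell growth factor FLT3 ligand, 2.53-fold lower and Dok1 2.27-fold lower. With the trend removed Kit, Flt3 and Dok1 differed by -0.81, -0.85 and -0.77, each more than the probe set SD. They were named for their size among the 18 members, and the largest of a list can pass that SD by probe noise alone, so this decides little. With the trend removed the transcription factors Maf and Cebpb, named after their values were seen, were the furthest apart, higher by 1.42 and 1.06.

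The 12 genes with the largest higher reading in Il34LacZ/LacZ included S100a8, S100a9, Pf4 and Acod1. S100a8 and S100a9, which encode the calprotectin subunits of neutrophils and monocytes, read 71.9 and 103.2 in Il34+/LacZ against 552.1 and 698.6 in Il34LacZ/LacZ, or 6.46-fold and 5.99-fold higher. Pf4, a chemokine of platelets and some macrophages, was 6.04-fold higher (148.1 against 975.3). Acod1, the itaconate-producing enzyme of activated macrophages, was 4.55-fold higher (94.0 against 484.7). Clec4b1, a C-type lectin receptor of dendritic cells, was below the floor in Il34+/LacZ and at least 4.47-fold higher at 273.4, and Slfn4, a Schlafen family gene of myeloid cells, was at least 3.79-fold higher. Rida, an enzyme that clears reactive imines, was below the floor in Il34+/LacZ (25.7 against 523.1, at least 8.33-fold higher) and Carnmt1, a carnosine methyltransferase, was 5.45-fold higher. The other 4 were small RNA genes: Snord61 (7.90-fold), Mir341 (7.35-fold), Snora16a (at least 5.86-fold) and the 5S ribosomal RNA gene n-R5s136 (5.92-fold). All 12 stayed at least 2-fold higher in the 9 settings computed per gene, the smallest being Carnmt1 at 1.06 on the log2 scale. Settings that changed only the floor could not alter a gene's value, nor could the probe set rule for genes with a single probe set. The genes were also picked for their size on these same arrays.

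The 12 largest lower readings in Il34LacZ/LacZ were led by keratinocyte genes. Krt14 and Krt5, the keratins of basal keratinocytes, read 787.4 and 1187.5 in Il34+/LacZ against 58.6 and 138.0 in Il34LacZ/LacZ, or 10.8-fold and 7.82-fold lower. Krt1, a keratin of differentiating keratinocytes, was at least 6.67-fold lower, and Ly6d was 9.74-fold lower. The heat shock protein gene Hsph1 was 7.10-fold lower (949.8 against 120.0). Slirp and Timm17a, both of mitochondria, were 7.29-fold and 6.01-fold lower, Tmx2 at least 5.97-fold, the chromatin remodelling subunit Pbrm1 at least 5.06-fold and the spliceosomal cyclophilin Ppih at least 4.67-fold lower. The remaining 2 were small RNA genes, Scarna17 (7.82-fold) and Mir142 (at least 3.70-fold). All 12 stayed at least 2-fold lower in the same 9 settings, with the same limits, the smallest being Ppih at 1.71 on the log2 scale.

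**Figure D2:**
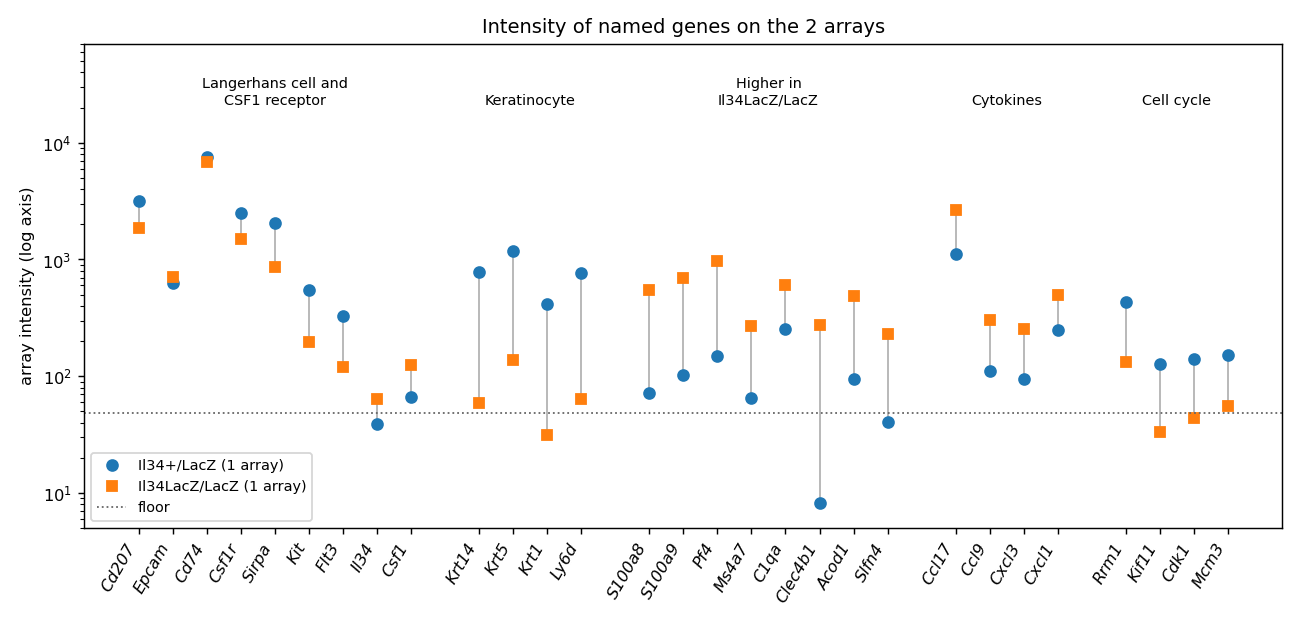
Array intensity (log axis) of named genes in Il34+/LacZ (circles) and Il34LacZ/LacZ (squares), 1 array each; the dotted line is the floor of 48.7. Keratinocyte genes sit lower in Il34LacZ/LacZ (Krt5 1187.5 against 138.0), and S100a8, S100a9 and Pf4 sit higher. Epcam differs by 0.16 on the log2 scale as deposited and by 0.77 with the trend removed.

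Keratinocyte genes as a list lay outside the central 95% of random lists only with the trend removed, and most fibroblast, endothelial and B cell markers were near the floor. Of 26 measured keratinocyte genes, 12 were at least 1.5-fold lower in Il34LacZ/LacZ and 2 at least 1.5-fold higher. The median of -0.51 lay at the 2.83 percentile, and at 0.12 with the trend removed, where 10 were lower and 1 higher. With the floor at the 75th percentile the median was -0.92. The epidermal gene Lgals7, chosen after its values were seen, read 128.2 and 129.4. Fibroblast genes had a median of 0.57 over 8 genes (97.67 percentile), but with the floor raised to the 75th percentile only Thy1, also on the T cell list, was left, at -0.35. Endothelial genes had one of 0.69 over 8 (98.56 percentile), but with that floor only Vwf was left, at -0.28. Thy1 and Vwf were named after their values were seen. Col1a2, a collagen chain, read 55.2 and 107.4 and the endothelial cadherin Cdh5 40.4 and 98.3. With the trend removed the fibroblast median was 0.47 (98.12 percentile) and the endothelial one 0.41 (96.28 percentile). Melanocyte, mast cell and B cell lists had medians of 0.45 (5 genes), -0.14 (3 genes) and 0.17 (6 genes), or 0.29, -0.33 and -0.12 with the trend removed, all within the central 95% of random lists. With the raised floor the melanocyte median was -0.26, over Sox10 and Kit, and the mast cell list held only Kit, at -1.41. Sox10 of melanocytes read 64.4 and 134.1, Gata2 of mast cells 64.4 and 88.0, and Ighm of B cells 52.5 and 77.1. The single erythroid gene measured, Slc4a1, read 49.3 and 68.9.

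Inflammatory genes ran above genes of the same level in Il34LacZ/LacZ, and macrophage genes lay above the central 95% of random lists only with the trend removed. Of 17 measured macrophage genes, 4 were at least 1.5-fold higher and 3 lower, with a median of 0.20 (94.20 percentile). After removal of the trend 6 were higher and 2 lower, with a median of 0.35 (98.70 percentile). Pf4 led the list, Ms4a7 was 3.54-fold higher (64.8 against 270.0) and the complement gene C1qa 2.26-fold higher (256.2 against 598.8), whereas the chemokine Ccl8 was at least 1.16-fold lower. Of 16 monocyte genes, 4 were higher and 4 lower, and the median was -0.04 (95.04 percentile) but 0.16 with the trend removed (83.86 percentile), when 5 were higher and 1 lower. The lectin receptor Clec4e was 2.40-fold higher and the interferon-induced membrane protein gene Ifitm3 1.86-fold higher, while Msrb1 was 4.19-fold lower and Plac8 1.77-fold lower. Of 22 inflammatory cytokines and NF-kB targets, 6 were higher and 3 lower. Their median of -0.00 lay at the 99.97 percentile, because genes of their level had a median of -0.46, and it was 0.43 with the trend removed (8 higher, 2 lower) and -0.15 with each array centred on its median. The neutrophil and monocyte attractants Ccl9, Cxcl3 and Cxcl1 were 2.51-fold, 2.44-fold and 1.93-fold higher, and the inflammasome sensor Nlrp3 was 2.07-fold lower. The neutrophil list (9 genes) had a median of 0.46 at the 94.37 percentile and of 0.16 at 68.60 with the trend removed. Over the settings its median ran from 0.16 to 1.05. Camp, a granule peptide, was at least 1.52-fold higher, and Stfa3, one of several near-identical stefin genes and so uncertain, was at least 2.05-fold lower. Keratinocyte genes ran the other way in the same comparison, with a median of -0.51.

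Antigen presentation and dendritic cell maturation genes lay within the central 95% of random lists of their level. Of 13 MHC class II genes, 5 were at least 1.5-fold lower and 1 higher (median -0.47, 54.68 percentile), but 2 lower and 1 higher with the trend removed (median -0.01). Ciita, the master regulator of class II genes, was 2.98-fold lower, H2-Eb2 1.69-fold and Ifi30, a lysosomal thiol reductase, 1.68-fold lower, while the protease gene Ctsl was 1.69-fold higher. Of 12 MHC class I genes, 6 were lower and none higher (median -0.59, 32.12 percentile), or 4 and none with the trend removed (median -0.02). They included the peptide transporter subunit Tap1 at 3.01-fold, H2-M3 at 2.34-fold, the trimming peptidase Erap1 at least 2.28-fold and the immunoproteasome subunit Psmb9 at 2.21-fold. Of 25 maturation and migration genes, 9 were lower and 4 higher. Their median was -0.41 (51.41 percentile) and 0.16 with the trend removed, when 3 were lower and 3 higher. Ccl17, a chemokine of dendritic cells that attracts T cells, read 1121.0 against 2639.9, 2.34-fold higher and 1.74 on the log2 scale with the trend removed. Anxa3 was at least 1.85-fold higher, while Serpinb6b and the apoptosis inhibitor Birc3 were 3.18-fold and 2.56-fold lower.

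Neither of the 2 interferon lists left the central 95% of random lists. Of 23 type I interferon genes, 7 were higher and 2 lower (median -0.03, 75.58 percentile, but 0.10 with the trend removed, when 8 were higher and 3 lower, and 0.61 with the raised floor). Rsad2, the antiviral protein viperin, was at least 2.40-fold higher, Oasl1 2.42-fold and Ifit1 at least 1.96-fold higher, while Irf9, a subunit of the interferon-activated transcription factor complex, was 3.07-fold lower. Of 8 interferon gamma genes, 5 were lower and none higher (median -0.71, 4.81 percentile), or 3 and none with the trend removed (median -0.41, 7.84 percentile). The chemokine Cxcl9 was 3.41-fold lower, the guanylate-binding protein gene Gbp7 1.99-fold, the costimulatory ligand gene Icosl 1.81-fold and Irgm1 1.78-fold lower. The difference between the 2 lists was not tested.

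Cell cycle genes were the lowest list relative to their level. Of 28 measured cell cycle genes, 20 were at least 1.5-fold lower in Il34LacZ/LacZ and none higher. The median of -0.91 lay at the 0.02 percentile, and at the 0.05 percentile with a median of -0.56 and 13 lower once the trend was removed. Rrm1, a subunit of ribonucleotide reductase, was 3.03-fold lower (434.7 against 132.9) and the replication helicase subunit Mcm3 2.38-fold lower, while the mitotic kinase Cdk1 and the mitotic motor Kif11 were at least 2.41-fold and 2.21-fold lower. Keratinocyte genes were lower in the same sample, with Krt14 10.8-fold lower. Cholesterol synthesis genes had a median of -0.89 (18 genes, 11 lower, none higher) at the 0.80 percentile. With the trend removed it was -0.32 at the 2.55 percentile, inside the central 95%, with 7 lower. Nsdhl and Dhcr7, enzymes of the pathway, were 3.13-fold and 2.84-fold lower, the sterol sensor partner Insig1 2.66-fold and the sterol carrier Stard4 2.49-fold lower. Unfolded protein response genes had a median of -0.88 (20 genes, 13 lower, none higher) at the 1.28 percentile. With the trend removed it was -0.29 at the 3.99 percentile, inside the central 95%, with 3 lower. Xbp1, a transcription factor of that response, was 2.36-fold lower, the chaperones Hspa5 and Hsp90b1 2.31-fold and 2.26-fold lower, and Sel1l 2.15-fold lower. Of 34 lists with a percentile, 3 lay below and 3 above the central 95% of random lists, or 2 and 4 with the trend removed. By chance 1.7 in all would be expected if members of a list varied as independently as randomly drawn genes. That was not tested, so the count does not show an excess.

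**Figure D3:**
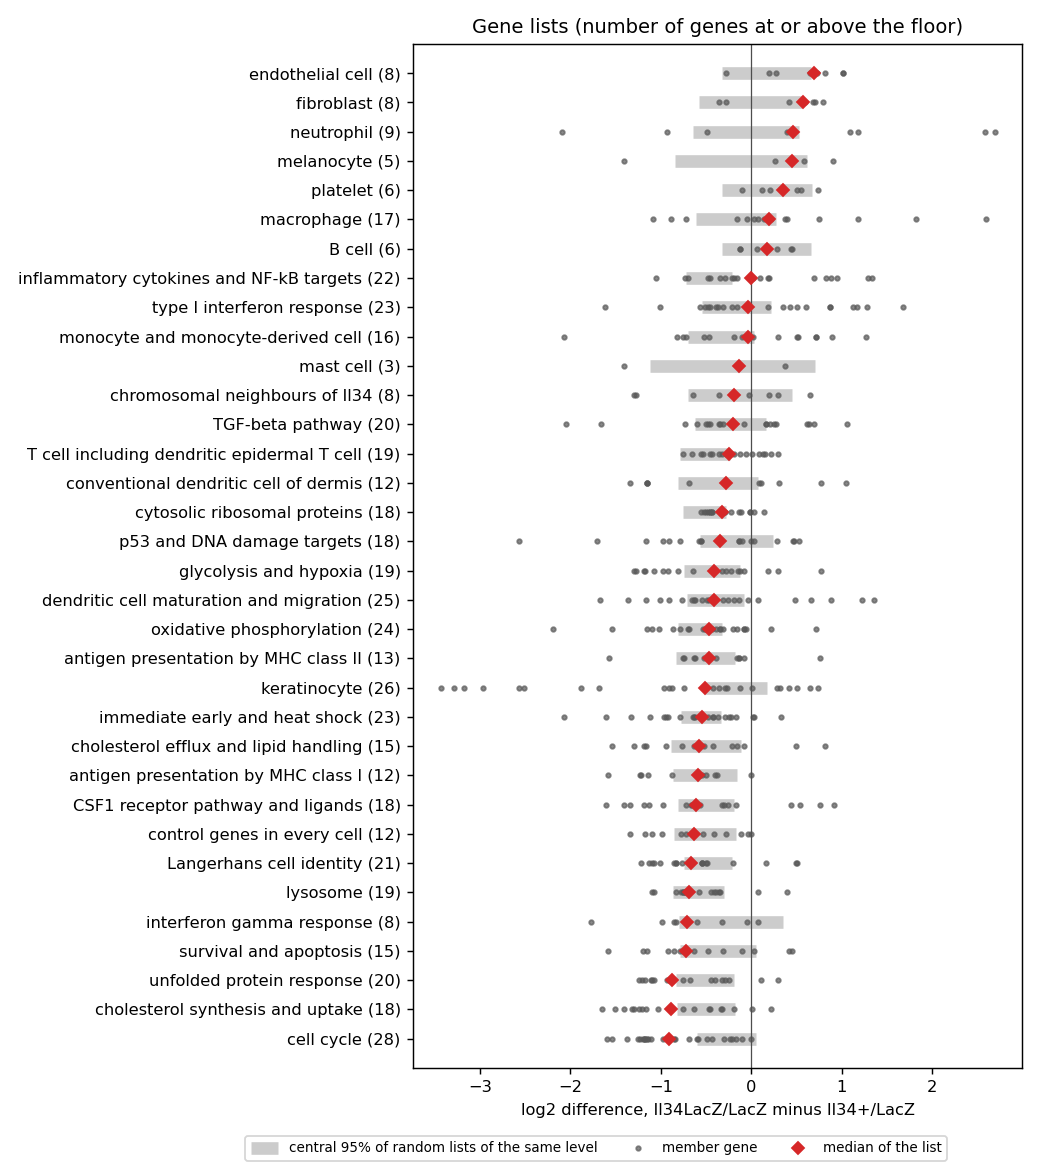
Log2 difference between Il34LacZ/LacZ and Il34+/LacZ (x) for each gene list (y, with its number of measured genes); grey dots are genes, red diamonds list medians, and grey bars the central 95% of 10000 random lists of the same level. The cell cycle median of -0.91 lies left of its bar, and the median of inflammatory cytokines lies right of it.

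Immediate early, survival, p53 and TGF-beta lists lay within the central 95% of random lists. Immediate early and heat shock genes, which respond to cell handling, had a median of -0.55 (23 genes, 46.56 percentile) and -0.03 with the trend removed. Within them the heat shock genes Dnajb1, Hspa1a and Hsp90aa1 were 4.19-fold, 3.04-fold and 2.51-fold lower, and the AP-1 gene Jun 2.18-fold lower. With the trend removed they differed by -1.44, -1.14, -0.82 and -0.66, whereas Hspa8 differed by 0.02. Survival and apoptosis genes had a median of -0.72 (15 genes, 5.59 percentile) and -0.22 with the trend removed, with the caspase inhibitor Cflar 2.99-fold, Bak1 2.30-fold, Xiap 2.22-fold and Bcl2 1.89-fold lower. The p53 target list had a median of -0.35 (18 genes, 18.84 percentile) and -0.32 with the trend removed (3.42 percentile), with Trp53inp1 3.27-fold and Gadd45b 2.24-fold lower, Sesn1 at least 1.86-fold lower, and Perp, also an epidermal adhesion gene, 5.92-fold lower. The TGF-beta list had a median of -0.20 (20 genes, 60.08 percentile) and 0.12 with the trend removed. In it the signal transducer Smad4 was 4.13-fold lower, the inhibitory Smad7 3.15-fold lower and Itgb8 at least 1.13-fold lower, while Smad6 was at least 1.37-fold higher.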

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

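The explanations and the tests of them in this part were chosen after the values had been seen, while the gene lists and the removal of the trend that they use were fixed before. Some probe sets stand outside the comparison and are given because they hold signal that it does not use. Of the probe sets with no gene symbol, 527 were at least 2-fold higher in Il34LacZ/LacZ than in Il34+/LacZ and 1069 were lower, among 5270 at or above the floor. Of those with more than 1 gene symbol, 31 were at least 2-fold higher and 104 lower, among 734 at or above the floor.

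The first pattern is that expressed genes were mostly lower on the Il34LacZ/LacZ array. A single scaling factor between the arrays is argued against, because the median difference was 0.30 between 16 and 48 intensity units and -0.65 between 240 and 496, a gap of 0.94 with opposite signs. An intensity scale compressed over the whole array is argued against as the only cause, because between 240 and 496 the 662 probe sets with no symbol had a median of -0.30, which is 0.34 above that of probe sets with 1 symbol (standard error over probe sets 0.06). Those with no symbol still ran the same way with level, at 0.12 between 16 and 48. Between 1008 and 2032 they were at -0.43, against -0.53 with 1 symbol. Such a compression therefore stays open as part of the cause. Less messenger RNA per cell stays open, because arrays loaded with a fixed amount of RNA do not show it and the control genes' median of -0.63 decides nothing. A genotype effect on many transcripts also stays open, untested.

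The second pattern is the lower level of keratinocyte transcripts in Il34LacZ/LacZ. The trend with level is argued against as its cause, because with the trend removed the median was -0.46 in place of -0.51 and lay at the 0.12 percentile of random lists. As deposited it lay at 2.83, inside the central 95%. More keratinocyte RNA in the Il34+/LacZ sample, bound to cells or carried through the sort for Langerin and Epcam, may contribute and stays open, because 10 of 26 members were at least 1.5-fold lower with the trend removed, while Lgals7 and Dmkn, chosen after their values were seen, read 128.2 and 129.4, and 256.5 and 176.4. Some members that were not lower lay near the floor, such as Krt6a (48.3 and 69.7) and Krt17 (33.4 and 61.7), and decide little. Lypd3, above the floor on both arrays, ran the other way at 88.8 and 159.0, a difference of 0.99 with the trend removed. Krt10, also chosen after its values were seen, read 536.8 and 81.2. A difference of genotype in the Langerhans cells themselves was not tested and stays open with 1 array each.

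The third pattern is the higher level of S100a8, S100a9, Pf4 and the other genes with the largest differences in Il34LacZ/LacZ. Of these 12 genes only S100a8, S100a9 and Pf4 are on a gene list. The list results below therefore do not bear on the other genes, such as Rida, Carnmt1 and the small RNA genes. The trend with level is argued against, because at the level of 11 of the 12 genes it ran the other way, lower in Il34LacZ/LacZ. Clec4b1, the exception, was at least 4.47-fold higher as deposited. By level the median difference was at most 0.30, so genes picked for differences this large could not have owed them to the trend. The selection thus settled this outcome beforehand. Neutrophil RNA stays open: the 7 other neutrophil genes at or above the floor lay at the 48.34 percentile with the trend removed, but only 6 of 14 reached the floor in Il34LacZ/LacZ. A larger share of monocyte-derived cells or macrophages may contribute and also stays open. With the trend removed the monocyte list lay at the 83.86 percentile and the macrophage list at 98.70. The macrophage list kept Pf4, one of the genes to be explained, so its percentile is not independent of the pattern. A change of expression within Langerhans cells was not tested.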

How the results depend on the processing

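No library could be left out, because each genotype has 1 array; for the same reason no split of the samples could be counted. No paired analysis was possible because each genotype has a single sample. Against 327 genes at least 2-fold higher as deposited, there were 188 with the floor at the 75th percentile, 161 with each sample centred on its median, 564 after quantile normalization, 530 with the loess trend removed, 856 with a pseudocount of 1 and 72 with a pseudocount of 64. Against 1685 genes at least 2-fold lower, there were 858 after quantile normalization, 892 with the loess trend removed and 850 with a pseudocount of 64. Of the 2 alternatives chosen after seeing the data, the loess trend removed together with the floor at the 75th percentile gave 502 higher and 519 lower, and leaving out keratinocyte and small RNA genes gave 310 higher and 1650 lower. The other settings stayed within 1.5 times. Centring moved the median of all genes from -0.16 to -0.33, and the loess and quantile scalings moved it to 0.03. Higher genes made up 6.4% of those apart after centring and 39.7% after quantile normalization. With the floor at the 75th percentile, 28 of 33 list medians stayed within the probe set SD of their value and 4 moved further. The remaining one, of the endothelial list, changed sign to -0.28, since it then rests on Vwf alone. The fibroblast and melanocyte medians also changed sign there, to -0.35 and -0.26. The probe set SD is that of a single gene and is wide for a median of many genes, so these counts show little about stability. The keratinocyte median, -0.51 as deposited and -0.92 with the raised floor, counted as staying. Of 158 named genes, 142 stayed within the probe set SD of their value with the trend removed and 16 moved further. Trend removal shifts a gene only by the trend at its level, at most about the probe set SD, so this count shows little. For the same reason no gene at least 2-fold apart could change sign. Several of those fell below 2-fold, such as Sirpa (-1.215 to -0.673), Ciita (-1.576 to -0.961) and Hspa5 (-1.207 to -0.662), while Krt14 stayed at -2.894. The alternative on probe set name endings was not run, because this array's probe sets have none. Dim genes limit the comparison, since no detection calls were used here. The cause of the other changes was not tested.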

Other observations

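Several T cell transcripts were read far above the floor in both samples although the sort was for Langerin and Epcam, while Cd4 read 104.2 and 55.0. Cd3e, a subunit of the T cell receptor complex, read 1245.4 in Il34+/LacZ and 1250.3 in Il34LacZ/LacZ, and Thy1, a marker of the gamma delta T cells of mouse epidermis, 2664.1 and 2081.7. Both were chosen after their values were seen. Of 19 measured T cell genes, 2 were at least 1.5-fold lower in Il34LacZ/LacZ and none higher, with a median of -0.25 (96.77 percentile) and 0.28 with the trend removed (97.72 percentile), when 5 were higher and 1 lower. Cd4 was 1.69-fold lower, the cytokine receptor chain Il2rb 1.57-fold, Cd247 1.47-fold and the adaptor Lat 1.45-fold lower. With the trend removed Cd4 differed by -0.85, Il2rb by -0.04, Cd247 by -0.06 and Lat by 0.09. Dermal dendritic cell genes had a median of -0.28 over 12 genes (67.74 percentile) and 0.12 with the trend removed. Of them 5 were at least 1.5-fold lower and 2 higher, or 3 and 2 with the trend removed. Kmo, Wdfy4 and the integrin gene Itgae were 2.23-fold, 2.22-fold and 2.22-fold lower. Platelet genes, a list chosen after the first values were seen, had a median of 0.36 over 6 genes (56.66 percentile) and 0.14 with the trend removed, and Ppbp, abundant in platelets, read 35.9 and 57.8.

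Of 4 sex-linked genes with a probe set, only Xist and Eif2s3y were at or above the floor, and both were so in both samples. The Y-linked reading thus rests on Eif2s3y alone. Xist, made from the inactive X chromosome of females, read 617.4 in Il34+/LacZ and 134.2 in Il34LacZ/LacZ, and the Y-linked Eif2s3y read 197.1 and 93.8. With the trend removed Xist and Eif2s3y differed by -1.49 and -0.63. The sex and number of animals per array are not in the labels, so a difference in sex between the arrays cannot be separated from genotype. Of 8 measured neighbours of Il34, 3 were at least 1.5-fold lower and 1 higher, with a median of -0.19 (39.07 percentile) and -0.07 with the trend removed. Over the settings the median ran from -0.65 to 0.04, the latter after quantile normalization. The adjacent genes Sf3b3 and Mtss2 were 2.45-fold and 1.57-fold lower, Cog4 at least 2.13-fold lower and Clec18a at least 1.49-fold higher.

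Oxidative phosphorylation genes had a median of -0.46 (24 genes, 78.30 percentile) and 0.08 with the trend removed, with Atp5g1 4.59-fold, Uqcrc2 2.92-fold, Uqcrq 2.22-fold and Sdha 2.14-fold lower. Of the list 9 were at least 1.5-fold lower and 1 higher, or 2 and 2 with the trend removed. Uqcrq and Sdha then differed by -0.535 and -0.498, within the probe set SD. Glycolysis and hypoxia genes had a median of -0.41 (19 genes, 61.64 percentile) and -0.15 with the trend removed, with Hif1a 2.45-fold and the glucose transporter Slc2a1 2.43-fold lower. Lipid handling genes had a median of -0.58 (15 genes, 36.41 percentile) and -0.19 with the trend removed, led by the cholesterol transporter Npc1 at 2.92-fold lower. Lysosome genes had a median of -0.69 (19 genes, 19.84 percentile) and -0.14 with the trend removed, when 1 was at least 1.5-fold lower and 2 higher, with Ctsa 2.15-fold and Grn 2.11-fold lower. Ribosomal protein genes stayed within 1.5-fold in 18 of 18 cases (median -0.32, 95.20 percentile, 0.10 with the trend removed). Control genes had a median of -0.63 (12 genes), or -0.16 with the trend removed, and lay within the central 95% of random lists, with Hprt 2.54-fold and Tubb5 2.26-fold lower.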
